A study of Danio rerio with 12 samples.

How the data were processed

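Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in whole wild-type zebrafish embryos of a mixed AB and Tuebingen background at 6 hours post fertilization, around the onset of gastrulation. Per the labels' protocols, newly fertilized eggs were exposed to 3.12 µM TDCIPP (tris(1,3-dichloro-2-propyl) phosphate, an organophosphate flame retardant), to 100 µM decitabine (DAC, a cytidine analog that traps DNA methyltransferases) or to 0.1% DMSO, the solvent. The 12 libraries fall into 4 groups of 3, namely TDCIPP, its DMSO controls, DAC and its DMSO controls, and each treatment had control libraries of its own. The labels number the libraries of a group 1 to 3 but do not say whether they came from separate clutches, so the p-values measure the spread between these libraries, which may be technical.

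The submitters' processing notes name Bowtie2, Picard, MACS2, deepTools and DiffBind, without versions, and the genome build GRCz11. Whether reads were shifted for the Tn5 cut, how duplicates and reads with several matches were treated, and how libraries were normalized are not given in the sources used here. There are 2 deposited tables, 1 per treatment, each a DiffBind comparison over its own set of consensus regions. Per the file headers, each region has a level, which is the log2 of the mean normalized read count over all libraries, the same log2 value for the treated and the DMSO group, and a log2 fold. In every region of both tables the log2 fold in the authors' deposited tables equals the treated minus the DMSO level within 0.01, so a positive fold means higher accessibility after treatment. Per the file headers, each region also has an unadjusted p-value and an adjusted p-value (FDR), and the engine behind these deposited p-values is not given in the sources used here. The header of the DAC table names its treated group 5AzaC (5-azacytidine, another cytidine analog) where the labels name decitabine, and the group is called DAC here after the labels.

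The deposited tables hold 0 columns for single libraries, so no SD, no standard error, no test across replicates and no check of replicate similarity could be computed, and the depth per library is known only as a group mean. Summed over regions, the normalized reads per library came to 7.75 M for TDCIPP and 7.91 M for its DMSO controls, and to 2.07 M for DAC and 1.88 M for its DMSO controls. The median region had 83.9 normalized reads in the TDCIPP table and 18.1 in the DAC table. In the TDCIPP table, all 9402 regions with a level below 5.71 have an adjusted p of 1, including 583 regions with an unadjusted p under 0.05. The 25638 regions at or above that level were therefore the background of the tests of place and of neighbouring calls after TDCIPP. Where calls were joined, this background kept a single call of each group.

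A test on read counts had been fixed before the data were examined for the case that counts per library were at hand. As fixed for tables that hold only a comparison, the authors' adjusted p under 0.05 was used as the call. The share of calls with higher accessibility was given with a 95% Clopper-Pearson interval, which covers counting error only, because neighbouring regions are not independent. Calls were counted per chromosome, on alternate scaffolds (other haplotypes of placed sequence) and on unplaced sequence with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 54 tests of a comparison, and again after calls of the same direction within 50 kb had been joined. The share of calls with another call of the same direction within 50 kb was set against 10000 draws of regions matched on level in 20 classes (1000 draws for DAC). Regions of the 2 tables were paired where they shared at least 1 base, each region being used once. Pearson and Spearman correlations of the folds across paired regions were computed as such and after removal of the median within 100 joint classes of level. The DAC folds of called TDCIPP regions were set against 10000 draws, matched on level, from the uncalled regions and the set itself.

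The rule for named regions was fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among called regions at or above the median level, and the 2 with the smallest p in each direction, and, where nothing is called, the regions with the smallest p, given as not passing. Its parts on transcription start sites and genes could not be applied, because the only gene table at hand follows another build (GRCz12tu), and coordinates were not carried between builds. For the same reason, the shares of promoters and repeats and 18 gene lists were not analysed here. Groups of neighbouring calls, 1-Mb windows and high-level regions named outside that rule were chosen after their values were seen.

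Alternatives were stricter and looser thresholds, a fold minimum, recomputed adjustment, a level minimum, the 25 assembled chromosomes only, centred folds and, chosen after seeing the data, joined calls and level matching. The adjustment, the correlation of folds, the neighbour draws, the pairing of regions, the matched draws of folds, the place tests and the window correlation were tested on simulated data. Over 35040 simulated regions, the adjustment recovered 100% of planted regions with 11 other calls. Over 24956 simulated regions, folds that followed opposite level trends alone gave r = -0.179, and 0.0016 within classes of level. These simulated trends were steps over the same level classes, so their removal was built in, and trends inside a class were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.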

Results

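Chromatin accessibility at 6 hours post fertilization was compared between embryos exposed to TDCIPP or DAC and their own DMSO controls, with 3 libraries in each of the 4 groups. The series title concerns the histone variant H2A.Z and the release of repetitive elements from silencing, and the comparisons ask which regions gained or lost accessibility under each compound. Coordinates are on GRCz11. The deposited tables hold group means, folds and p-values without values of single libraries, so the spread between replicates enters only through the authors' own p-values.

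After TDCIPP, called regions were more often lower than higher, and the falls lay mostly at regions with a high read level, many of them beside another fall. In the authors' deposited table, 448 of 35040 regions passed an adjusted p of 0.05, of which 127 were higher and 321 lower than in DMSO (28.3% higher, 95% Clopper-Pearson interval 24.2 to 32.8). The split depended on the threshold and on level: 18.1% were higher at an adjusted p under 0.01, and 1672 of 3480 regions (48.0%) at an unadjusted p under 0.05 in the authors' deposited table. Of 10 level classes of equal size, the upper 2 (level 7.63 and above) held 249 falls and 38 rises, while classes 3 to 5 (level 5.50 to 6.39) held 12 falls and 36 rises. Regions that fell had a median log2 fold of -0.48 (range -1.07 to -0.31) in the authors' deposited table and a median level of 8.8, against a median level of 6.85 over the 25638 regions that could be called. Their median width was 2039 bp, against 1327 bp over the regions that could be called, and level counts reads over the whole region. Regions that rose had a median log2 fold of 0.66 (range 0.38 to 1.22) and a median level of 7.07 in the same authors' deposited table. Most changes were small, since 7 rises and 3 falls reached an absolute log2 fold of 1.

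Among regions that rose, chromosome 13 at 48343337 to 48346296 had the largest fold by the naming rule, with a log2 fold of 1.22 and an adjusted p of 3.33e-06 in the authors' deposited table. The rise with the smallest p lay on chromosome 19 at 25744330 to 25745719, with a log2 fold of 0.94 and an adjusted p of 3.26e-07 in the authors' deposited table. Further rises lay on chromosome 18 at 20297272 to 20298613 (log2 fold 0.95), chromosome 4 at 60310257 to 60312524 (0.88) and chromosome 17 at 34909773 to 34910637 (0.83), all from the authors' deposited table. The remaining large rises, by the authors' deposited table, were an alternate scaffold of chromosome 1 at 212679 to 213746 (1.07), chromosome 23 at 23076547 to 23077129 (0.81) and chromosome 3 at 35372535 to 35373960 (0.81).

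Among regions that fell, chromosome 10 at 44994572 to 44997297 had the smallest p of the authors' deposited table, with a log2 fold of -0.98 and an adjusted p of 1.32e-09. A second region of that chromosome, at 29854217 to 29855758, had a log2 fold of -0.92 in the authors' deposited table. On chromosome 19, the region at 5368451 to 5370464 fell by 0.86 on the log2 scale with an adjusted p of 3.32e-08 in the authors' deposited table, and 4 falls lay together there between 5335124 and 5370464. The largest fall by the naming rule lay on chromosome 23 at 42297232 to 42298043, with a log2 fold of -1.03 and an adjusted p of 0.00136 in the authors' deposited table. Other large falls in the authors' deposited table lay on chromosome 17 at 20537620 to 20538765 (-0.89), chromosome 1 at 34706462 to 34708518 (-0.89) and chromosome 24 at 22644490 to 22646356 (-0.88). An alternate scaffold of chromosome 17 at 165917 to 167498 had a log2 fold of -0.88 in the authors' deposited table.

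**Figure D1:**
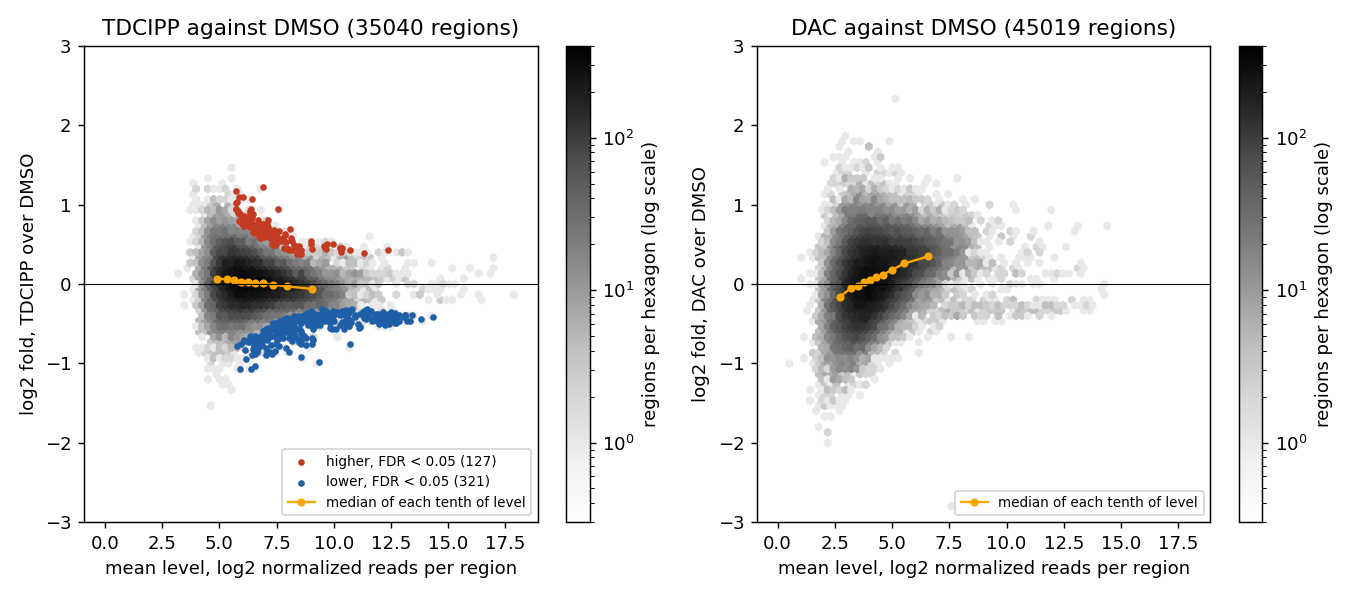
Log2 fold over DMSO (vertical axis) against mean level in log2 normalized reads per region (horizontal axis) for TDCIPP, left, and DAC, right, with grey hexagons for numbers of regions on a log scale. Red and blue points are the 127 higher and 321 lower regions after TDCIPP, no region passed after DAC, and the orange line of medians over 10 level classes of equal size goes from 0.07 to -0.06 for TDCIPP and from -0.16 to 0.35 for DAC.

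Many falls after TDCIPP lay close to another fall, while most had none within 50 kb. After joining within 50 kb, the 321 falls made 215 places, of which 179 held a single fall. Of the 321 falls, 142 (44.2%) had another fall within 50 kb, while draws of regions matched on level gave a median of 9.35% and at most 19.6% (permutation test over regions, one-sided, p = 0.0001, the smallest that 10000 draws can give). Of the 127 rises, 14 (11.0%) had another rise within 50 kb, against at most 9.45% in the draws (permutation test over regions, one-sided, p = 0.0001), and the difference between falls and rises was not tested. There were 9 places with at least 6 falls, which together held 77 falls, or 24.0% of all. The longest run lay on chromosome 5 from 43119823 to 43285793, where 12 regions fell with a median log2 fold of -0.46 in the authors' deposited table. Chromosome 25 held 2 such places, from 36309759 to 36370470 with 11 falls (median -0.39 in the authors' deposited table) and from 35048760 to 35152330 with 10 falls. Chromosome 7 held 3, from 6424981 to 6468780 with 7 falls, from 5903940 to 5978158 with 6 and from 73813205 to 73859486 with 6. Chromosome 17 held 9 falls from 23329700 to 23382391, and 2 alternate scaffolds of that chromosome held 9 and 7 falls. Within these 9 places, median folds ranged from -0.47 to -0.39 in the authors' deposited table. Without them, 244 falls were left and the share of rises among calls was 34.2%.

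**Figure D2:**
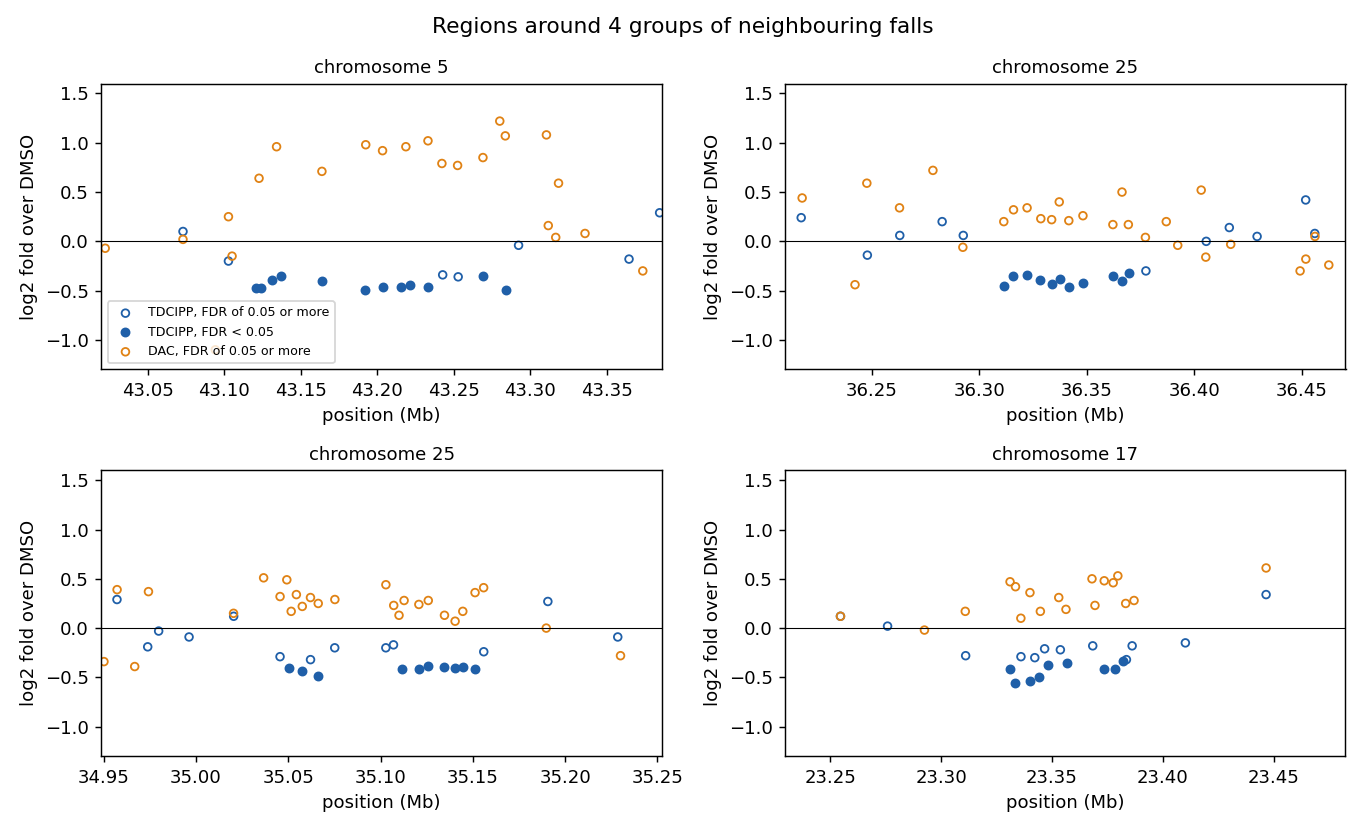
Log2 fold over DMSO (vertical axis) of each region by position in Mb (horizontal axis) around the 4 places on assembled chromosomes with the most falls after TDCIPP, which held 12, 11, 10 and 9 falls. Filled blue points passed an adjusted p of 0.05 after TDCIPP, open blue and orange points are regions of the TDCIPP and DAC tables that did not pass, and within the 4 places the blue points lie below 0 and the orange points above it.

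Chromosomes differed in their number of calls. Chromosome 4 held 3 of the 321 falls but 6.62% of the regions that could be called (odds ratio 0.131, Fisher's exact test, adjusted p = 3.28e-05), and this held with neighbouring calls counted once (odds ratio 0.197, adjusted p = 0.0131). Rises were more frequent on chromosome 17, with 14 of 127 (odds ratio 3.72, Fisher's exact test, adjusted p = 0.00129; 0.00753 with neighbours counted once). Chromosome 25 held 27 falls (odds ratio 3.74, Fisher's exact test, adjusted p = 1.97e-06) and chromosome 19 held 26 (odds ratio 2.44, adjusted p = 0.0013), but neither passed once neighbouring calls were counted once (odds ratios 1.37 and 2.08, adjusted p = 0.743 and 0.143). The excess of falls on chromosomes 5 and 7 (Fisher's exact test, adjusted p = 0.0168 and 0.0438) was lost in the same way (0.743 and 0.894), and chromosome 18, without a fall, went from an adjusted p of 0.00769 to 0.143.

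After DAC, no region passed. In the authors' deposited table, the DiffBind adjusted p was 1 at all 45019 regions, 453 regions (1.01%, where an even spread of p gives 5%) had an unadjusted p under 0.05, and the smallest unadjusted p was 0.000123. Of these 453, 340 had a positive and 113 a negative fold (75.1% positive, 95% Clopper-Pearson interval 70.8 to 79.0). Positive folds also prevailed over the whole DAC table, at 59.8% of all 45019 regions with a median of 0.10 in the authors' deposited table. With TDCIPP, 3480 regions (9.93%) had an unadjusted p under 0.05 in the authors' deposited table. Regions with an unadjusted p between 0.04 and 0.06 had a median absolute log2 fold of 0.98 in the DAC table and 0.39 in the TDCIPP table, both being the authors' deposited tables. The median log2 folds called after TDCIPP, -0.48 and 0.66 in the authors' deposited table, were smaller in size than 0.98, though the largest reached -1.07 and 1.22. Whether such changes could be detected after DAC at the level of the called regions was not tested.

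**Figure D3:**
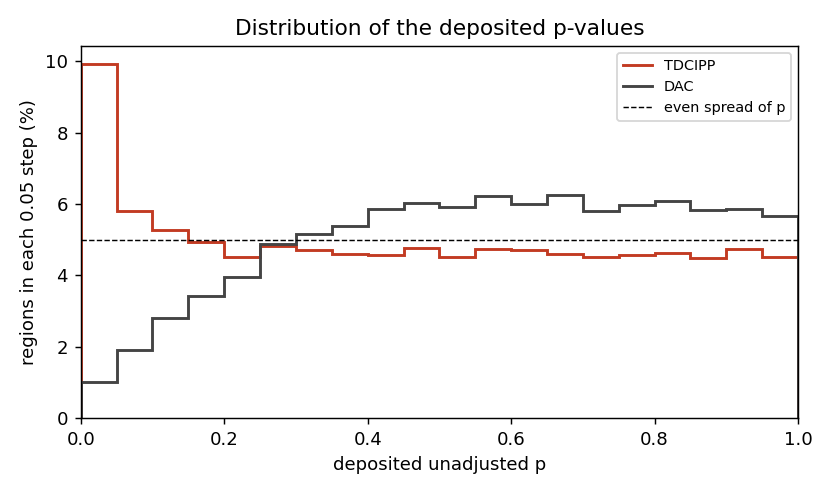
Percent of regions (vertical axis) in each 0.05 step of the deposited unadjusted p (horizontal axis) for TDCIPP (red) and DAC (dark grey), with a dashed line at the 5% of an even spread. The first step holds 9.93% of regions for TDCIPP and 1.01% for DAC.

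The regions with the smallest p after DAC are given as not passing. On chromosome 25 the region at 31468689 to 31469204 had a log2 fold of 1.80 and an unadjusted p of 0.000123, with an adjusted p of 1, in the authors' deposited table. Chromosome 7 at 11988676 to 11989761 had a log2 fold of 1.75 (unadjusted p = 0.000339) and chromosome 16 at 25708442 to 25710872 had 1.59 (unadjusted p = 0.000414) in the authors' deposited table. On the negative side, chromosome 11 at 22164190 to 22165195 had -1.63 (unadjusted p = 0.00572) and chromosome 15 at 14816474 to 14818381 had -1.17 (unadjusted p = 0.00703) in the authors' deposited table. The most negative of them, chromosome 24 at 42143266 to 42146469, had a log2 fold of -2.78 with an unadjusted p of only 0.00888 in the authors' deposited table. Alternate scaffolds held 70 of the 340 regions with a positive fold at an unadjusted p under 0.05, against 9.77% of all regions (odds ratio 2.42, Fisher's exact test, adjusted p = 1.04e-07). As a class, all regions on alternate scaffolds had a median DAC fold of 0.2, against 0.1 on assembled chromosomes, in the authors' deposited table. Of the 113 with a negative fold, chromosome 24 held 12 (odds ratio 4.58, Fisher's exact test, adjusted p = 0.000896) and chromosome 17 held 11 (odds ratio 3.19, adjusted p = 0.0228). Chromosome 4 held 1 of these 113 (odds ratio 0.113, Fisher's exact test, adjusted p = 0.044), which did not pass with neighbours counted once (adjusted p = 0.0672). Of the 340 regions with a positive fold, 45 (13.2%) had another such region within 50 kb. Level-matched draws gave at most 8.24% (permutation test over regions, one-sided, p = 0.001, the smallest that 1000 draws can give). Among the 113 with a negative fold, 4 (3.54%) had one, against at most 5.31% (permutation test over regions, one-sided, p = 0.0869). For these 113 the outcome depended on the distance. Within 10 kb, 4 had one, against at most 3.54% in the draws (permutation test, p = 0.005). Within 100 kb, 12 (10.6%) had one, against at most 8.85% (permutation test, p = 0.001). The chromosome 1 interval from 30776724 to 30928239 held 13 regions, all 13 with a positive DAC fold, and 6 of them had an unadjusted p under 0.05, with a median log2 fold of 1.12 in the authors' deposited table.

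Whether the compounds altered the same regions was asked at 24956 regions present in both tables. No region was called in both, and with 0 calls after DAC no overlap of calls could be tested. Regions with lower accessibility after TDCIPP tended to have higher DAC folds: across regions, which are not independent replicates, the folds of the authors' deposited tables had Pearson r = -0.149 and Spearman rho = -0.147. The correlation was below 0 on 25 of 25 chromosomes, from -0.265 on chromosome 21 to -0.005 on chromosome 4. Chromosome 4, with 1689 shared regions, thus had in effect no correlation. Within joint classes of level, r was -0.102. The 202 shared regions with a positive DAC fold at an unadjusted p under 0.05 showed no such tendency, with a median TDCIPP fold of 0, and 100 of them (49.5%) lay above 0, against 48.0% of all shared regions, in the authors' deposited tables. Only 10 shared regions had a negative DAC fold at that p, of which 8 had a TDCIPP fold above 0. Control levels of the 2 tables were correlated across the same regions (r = 0.787), with a median 2.3 higher on the log2 scale in the TDCIPP table.

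DAC folds of called TDCIPP regions were set against draws of the same level from uncalled regions and the set itself. Of 286 falls present in the DAC table, 271 (94.8%) had a DAC fold above 0, with a median of 0.41 in the authors' deposited table, while the matched draws gave a median of 0.34 and 88.5%. Of 76 rises, 39 (51.3%) had a DAC fold above 0, with a median of 0.01 in the authors' deposited table, against 0.27 and 77.6% in the matched draws. The falls lay at percentile 99.99 and the rises at percentile 0 of 10000 matched draws, which describe these libraries and not the spread between replicates. In the 9 places with at least 6 falls, 100 of 101 DAC regions had a fold above 0, against 75.5% of uncalled shared regions. Median DAC folds of these places ranged from 0.21 on chromosome 7 (5903940 to 5978158) to 0.94 on chromosome 5 in the authors' deposited table. The 2 places of chromosome 25 had 0.23 and 0.25, below the 0.34 of the matched draws for all falls. The smallest unadjusted p of the chromosome 5 place was 0.0623 in the authors' deposited table. The 101 regions lie in only 9 places, and no draws were made for them alone. The rise on chromosome 19 at 25744330 to 25745719 was among the 39 with a positive DAC fold, which was 0.98 (unadjusted p = 0.0632) in the authors' deposited table. No DAC fold at these regions passed its own test, since the adjusted p was 1 throughout the authors' deposited table.

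**Figure D4:**
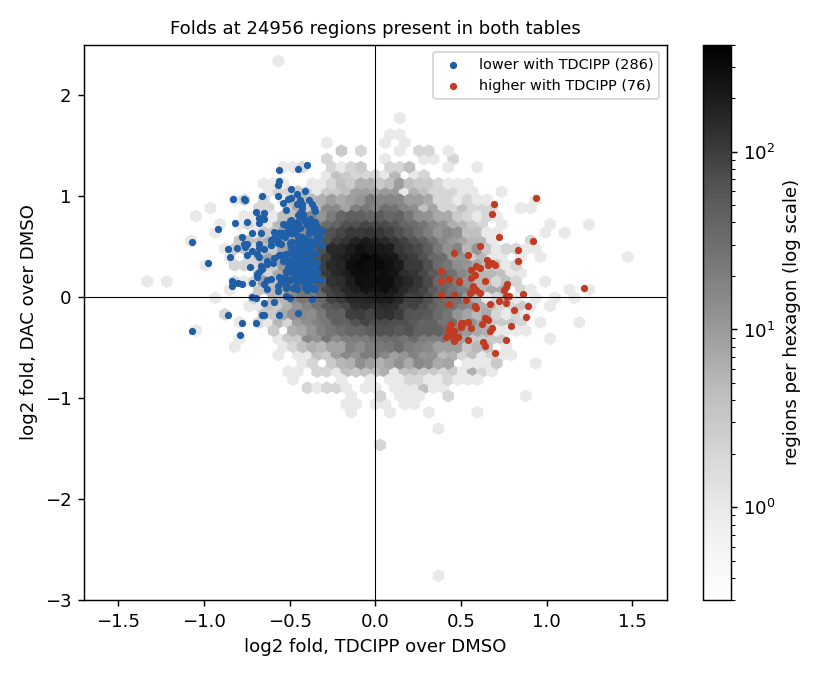
Log2 fold over DMSO after DAC (vertical axis) against that after TDCIPP (horizontal axis) at the 24956 regions present in both tables, with grey hexagons for numbers of regions on a log scale. Blue points (286 falls after TDCIPP) lie mostly above 0 on the DAC axis and red points (76 rises) lie around 0, with medians of 0.41 and 0.01. Level-matched draws gave medians of 0.34 for the falls and 0.27 for the rises.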

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

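Planned were the alternatives on both counts of calls, on their overlap, on the share of rises by threshold or centring, and on the correlation by shared bases or level minimum, except joined calls and omission of dense places. All other alternatives were chosen after seeing the data. So were the neighbour and chromosome results, the DAC results at unadjusted p and the DAC folds of called TDCIPP regions themselves. No paired analysis was possible because the tables hold no values of single libraries, and for the same reason leaving out libraries, other count tests, other library scalings, pseudocounts and other splits of the samples were not run. Promoter, repeat and gene list alternatives were not run either, for want of an annotation of the same build, and the share of DAC calls higher has no value with 0 calls. After DAC, 0 regions passed with recomputed adjustment, and the other alternatives on DAC calls and on the overlap could give only 0, because every adjusted p was 1. After TDCIPP, recomputed adjustment (410 regions), the level minimum, assembled chromosomes only, joined calls and omission of the dense places stayed within 1.5 times of 448. Stricter and looser thresholds gave 193 regions at 0.01 and 700 at 0.1, with 18.1% and 34.9% higher. An absolute log2 fold of at least 1 left 10 regions, 7 rises and 3 falls (70% higher). The direction of the split turned there, but on too few regions to show a reversal. Joined calls gave 35.6% higher and omission of the dense places 34.2%. The share of falls with a neighbour was 38.6% within 10 kb. At an unadjusted p under 0.05 after DAC, 70.3% were higher on assembled chromosomes, and 90.4% were higher at p under 0.01. The correlation of folds stayed negative under all alternatives, at -0.135 without called regions, -0.102 within level classes and -0.108 within level and width classes. The share of TDCIPP falls with a DAC fold above 0 went to 90.2% with centred DAC folds and 58.4% with level-matched ones, and that of rises to 35.5% and 22.4%. These last shifts came from taking off the median DAC fold, over all regions or within each joint level class. Median DAC folds rose from -0.16 in the lowest to 0.35 in the highest of 10 level classes in the authors' deposited table. Why DAC folds rose with level was not tested. The 16 named TDCIPP regions also passed with recomputed adjustment (highest adjusted p 0.0193). The DAC table had a median of 18.1 normalized reads per region, against 83.9 in the TDCIPP table.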

Other observations

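All tests in this part were chosen only after the results were seen. The DAC table was split at high level by the sign of the fold. Of its regions with a level of at least 8, 172 had a fold below 0, with a median of -0.29 (quartiles -0.34 to -0.24) in the authors' deposited table, and 332 had a fold of 0 or above, with a median of 0.39. Of the first set, 155 were present in the TDCIPP table, where 137 (88.4%) had a fold above 0 and 14 were rises and 0 falls. Of the second set, 320 were present, where 37.5% had a fold above 0 and 53 were falls and 0 rises. The smallest unadjusted p of the first set after DAC was 0.253 in the authors' deposited table.

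Median folds over longer stretches were also compared between the compounds. Over 1231 windows of 1 Mb with at least 10 regions in each table, level-matched median folds of the compounds had r = -0.275. The window of chromosome 17 from 46 to 47 Mb had level-matched medians of 0.34 after TDCIPP and -0.48 after DAC. Chromosome 8 from 34 to 35 Mb had 0.22 and -0.66. Other extreme windows had medians of the same sign, such as chromosome 25 from 21 to 22 Mb, the lowest after TDCIPP (-0.40 and -0.14), and chromosome 4 from 7 to 8 Mb (0.26 and 0.33). Over all windows, 676 had medians of opposite sign and 471 of the same sign. Chromosome 4 held 6.62% of regions in the TDCIPP table but 24.7% of the DMSO reads, and in the DAC table it held 14.1% of the DMSO reads. Alternate scaffolds had a level-matched median fold of 0.11 after DAC and -0.02 after TDCIPP.

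The folds of the compounds had a weak negative correlation across shared regions (r = -0.149). Regions with the smallest p after DAC and a positive fold showed no such tendency. Opposite trends with read level from class to class alone would leave r near 0 within classes of level. There it was -0.102 (95% interval -0.114 to -0.0897, which takes regions as independent), and width classes left -0.108. Trends that remained inside a class were not removed and stay open. The called regions alone would leave r near 0 without them, where it was -0.135. A difference in library quality or embryo stage between treated and DMSO libraries, running in opposite directions in the 2 experiments, also stays open and may give such folds. The high-level regions with a DAC fold below 0 had a median TDCIPP fold of 0.31. The same values may come from real opposite responses to the compounds, and these cannot be told apart without values of single libraries.

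Many falls after TDCIPP had another fall nearby. A higher read level would let draws matched in 20 level classes reach 44.2%, but the highest draw was 19.6%. Within the top class the draws were not matched further. Falls in the dense places had a median level of 11.87, and only 121 regions of the TDCIPP table reached level 12. Read level therefore stays open for those places. Loci repeated on alternate scaffolds would let the share drop on assembled chromosomes, where it was 44.9% against at most 18.4% in 2000 draws. Reads shared between near-identical copies stay open and could make neighbours alike, and the median SD of log2 folds within a place was 0.051, which either case allows. A hypothesis is that some places may be tandem histone gene arrays: in the GRCz12tu gene table, runs of at least 3 histone genes lay on chromosomes 7 and 25, with symbols such as hist1h2a11, hist2h3ca1 and hist1h4l, and of the 77 falls in all 9 dense places, 61 of them on assembled chromosomes, 40 (51.9%) lay on these chromosomes, which held 7.34% of the regions that could be called. These falls were chosen for lying in runs and make up only 5 places, so the shares are a description and not a test, and since the builds differ, whether the places hold these genes cannot be told.

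Small p-values were fewer after DAC than an even spread gives. A lower read level per region as the only cause would bring the share with p under 0.05 to 5% or more among the 4502 regions of highest level, where it was 0.222%. Read level as part of the cause also has values against it. In the TDCIPP table, the lowest of 10 level classes (3.31 to 5.14) had 6.28% of regions at p under 0.05. The highest DAC class began at level 5.93, above those regions though below the TDCIPP median of 6.39. The share was at most 1.42% in any DAC class and lowest in the highest one. These values argue against low read level for these classes, while other differences between the experiments were not separated. A spread between libraries of a group, which could come from a library that stood apart, stays open, because 0 columns hold values of single libraries. No biological explanation was tested for this pattern.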
